A study of Mus musculus with 4 samples.

How the data were processed

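The deposited values are raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 3.1.0 on mm10, per the file headers and labels; aligner settings and the annotation release were not stated. Each of the 4 libraries came as 1 count table over the same 27998 genes, and the lowest barcode totals lay near 500 UMIs. Gene coordinates came from GENCODE vM21, which held 27645 of the gene IDs.

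Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet at an expected rate of 0.05. Its automatic threshold was used for healthy brain (12 removed of 1400) and IgG (10 of 1444). For the other libraries it called under 0.5% of cells, a limit set after the data were seen, and the top 5% of scores were taken instead, which removed 90 of 1853 cells with anti-CTLA-4 and 169 of 3875 with depletion. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components and 15 neighbours went into Leiden clustering at resolution 1 over all libraries, without integration, which gave 22 clusters. T cells were clustered again on their own into 15 sub-clusters. For 1 test B cell-like and NK cell-like cells were each clustered on their own as well.

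Clusters were named from 29 marker lists fixed before the data were examined, by the markers among the 10 genes with the highest fold over all other cells and over cells outside the class. The names and classes themselves were given after seeing the clusters. Microglia are clusters 2, 3 and 11, and macrophages are clusters 1, 9 and 16, the last of them monocyte-like. Over all other cells the top 10 genes of cluster 11 held no listed marker and those of cluster 3 held 1, of astrocytes. Over cells outside the class cluster 11 held 2 microglia markers and cluster 3 held 5. Names are transcript-based likenesses, not sorted identities. T sub-cluster 9, counted as CD8-like, carried 2 NK markers and 1 CD8 marker among its top 10 genes over all other cells, and 2 of each over cells outside the class. CD4 T cells were those with a Cd4 UMI and no Cd8a or Cd8b1 UMI, and CD8 T cells the converse, both among T cells with any of the 3.

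For each class and comparison, UMIs were summed over the cells of a library and divided by their total (CPM). The ratio of 2 libraries carries an exact conditional-binomial 95% interval, shares carry exact Clopper-Pearson intervals, the limit beside a share of 0 is 3 counts of the total, and the intervals of list medians come from 2000 Poisson redraws. A ratio against 0 UMIs was taken against a floor of 3 counts per library and is a lower bound. The size rule, the naming rule, the 20 gene lists and the comparisons were fixed before the data were examined. A gene passed the size rule with at least 50 UMIs in both libraries together, a UMI in at least 10% of cells of the library where it was higher, and a CPM ratio of at least 2. Named are the 8 passing genes with the largest log2 ratio of CPM plus 5 in each direction, without ribosomal, mitochondrial, hemoglobin, immunoglobulin, T cell receptor segment and unnamed model genes. The 6 genes of the sex-linked list were also left out of counts and names, which the rule fixed beforehand did not say. Also named are 2 to 4 members of each list described, those with the largest ratio in size, and Cd4, Foxp3 and Ctla4. Ifi30 was named as the single member that went against its list.

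The lists cover MHC class II and class I presentation, interferon-gamma and type I interferon responses, homeostatic and disease-associated microglia, phagocytosis and complement, inflammatory cytokines and chemokines, immunosuppressive macrophages, costimulation, lipid handling, hypoxia and glycolysis, checkpoint and exhaustion, cytotoxicity, Th1, naive and memory, regulatory T, proliferation, dissociation response and sex-linked genes. A list's median log2 ratio was taken over members with at least 20 UMIs in both libraries together, with members counted at 1.5-fold. Its percentile came from 10000 random lists of the same size matched on expression. Clec7a, on the disease-associated list, was not in the table. T cell classes were compared only where both libraries held at least 50 cells, except CD8-like cells with IgG, of which there were 38.

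Alternatives were at least 500 genes per cell, no doublet removal, median-of-ratios size factors as DESeq2 computes them, ribosomal and mitochondrial genes left out of the total, cells thinned to 1000 UMIs, the mean of per-cell CPM, a ratio of 1.5, at least 20 UMIs with no minimum share, and resolutions 0.5 and 2. The resolution was changed only in the clustering of all cells, and T cells were clustered on their own at resolution 1 each time. Other clusters per class, and T sub-clusters on their own with at least 20 cells in both libraries, were tried after seeing the data. The comparison was run on 20 simulated pairs of libraries with known folds in 200 genes each. Both libraries of a pair were Poisson draws from a shared rate per gene, without clustering of UMIs by cell and without differences between pools. The shares below therefore check the calculation and cannot give the error of the rule on single pools. Its first form, a single pair, was replaced by the 20 after its result was seen, because interval coverage varied in so few genes. Of 120437 unchanged genes 393 (0.326%) passed the rule. Of genes changed 1.5-fold 85 of 1271 passed, of those changed 2.5-fold 1223 of 1346, and of those changed 4-fold 1346 of 1348. The intervals held the true ratio for 95.6% of unchanged genes. A list of 12 genes raised 2.5-fold had a median of 1.20 (true value 1.32, percentile 100), and 12 unchanged genes stood at percentile 62.9.

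Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 (with its Scrublet), anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.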

Results

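Single-cell RNA was measured with 10x Genomics droplets in immune cells from healthy mouse brain and from brains carrying glioma-005, a glioblastoma cell line implanted in the hippocampus of C57BL/6J mice. The 4 libraries held 1 group each: healthy brain, tumors given isotype control antibody (IgG), tumors given an antibody against CTLA-4, and tumors given anti-CTLA-4 plus an antibody that depletes CD4 cells. Antibodies were given from day 7 after implantation, tumors were collected at day 35, and each tumor library pooled 3 tumors. Within each library, 4 sorted fractions were mixed at equal ratios: microglia (CD45int CX3CR1+), myeloid cells (CD45hi CD11b+), T cells (CD45hi CD3+) and remaining immune cells. Barcodes carry no sort label, so the CD3 fraction and CD11b fraction below are groups of clusters named as T cells and as CD11b-type myeloid cells, and shares are given only within them. The healthy brain library held 7950206 unique molecular identifiers (UMIs) in 1420 barcodes, IgG 9952379 in 1484, anti-CTLA-4 13428840 in 1874 and depletion 21471565 in 3916. After filtering, 1388, 1434, 1763 and 3706 cells remained, with medians of 5059.5, 5853, 5655 and 4359 UMIs per cell in the same order. Groups had n = 1 library, so no comparison could be set against replicate error and none carries a p-value. Intervals (95%) and upper limits cover counting error only, and as UMIs of a gene cluster by cell, the true error is wider.

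T cells with Cd4 RNA were nearly gone from the depletion library. Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221, mm10), which encodes the antibody's target, stood at 79.0 CPM (its UMIs scaled to the total of the cells summed) in T cells of healthy brain, 141 with IgG, 134 (95% CI 122 to 147) with anti-CTLA-4 and 7.40 (95% CI 5.26 to 10.1) with added depletion. A Cd4 UMI was seen in 34.1% of T cells with IgG, 35.4% with anti-CTLA-4 and 1.59% with depletion. In B cell-like cells, which should lack it, the shares were 2.82%, 0 of 185 cells (up to 1.62% allowed by 3 counts) and 0 of 136 (up to 2.21%). Median depths were 5203.5, 5449 and 3949 UMIs in T cells and 5073, 4990 and 2753.5 in B cell-like cells, and the share left after depletion was not shown to differ from that background. Among T cells with a Cd4, Cd8a or Cd8b1 UMI, the CD4 share was 40.6% (41 of 101, 95% CI 30.9 to 50.8%) in healthy brain, 59.6% (134 of 225, 95% CI 52.8 to 66.0%) with IgG, 51.0% (176 of 345, 95% CI 45.6 to 56.4%) with anti-CTLA-4 and 2.26% (18 of 797, 95% CI 1.34 to 3.55%) with depletion. Cluster names in place of transcripts gave 17.1% for the last, because regulatory-like clusters count as CD4 there. The T cell cluster with conventional CD4 markers among its top genes (cluster 5) kept its share, with 28.5% (95% CI 24.7 to 32.5%) of T cells with anti-CTLA-4 and 27.2% (95% CI 24.7 to 29.9%) with depletion. A Cd4 UMI was seen in 75.2% and 3.68% of its cells, and a Cd8a or Cd8b1 UMI in 7.84% and 74.5%.

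Regulatory T cells made up a smaller part of CD4 T cells with anti-CTLA-4 than with IgG. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), the lineage factor of regulatory T cells, was seen in 34.3% (46 of 134, 95% CI 26.3 to 43.0%) of CD4 T cells with IgG and 21.02% (37 of 176, 95% CI 15.3 to 27.8%) with anti-CTLA-4, and in 2.44% (1 of 41, 95% CI 0.0617 to 12.9%) in healthy brain and 5.56% (1 of 18, 95% CI 0.141 to 27.3%) with depletion. The IgG and anti-CTLA-4 intervals overlapped. The level depended on the measure: by cluster names the shares were 74.4% with IgG, 54.9% with anti-CTLA-4, 80.5% with depletion and 85.7% in healthy brain. The cluster measure counts only regulatory-like and conventional CD4-like cells. It leaves out the type 2 lymphoid-like cells of sub-cluster 13, 29 with IgG and 3 with anti-CTLA-4, all of which lay in cluster 5. In cells thinned to 1000 UMIs the shares by transcripts were 16.7% with IgG and 6.15% with anti-CTLA-4. No Foxp3 UMI was seen in the 71 B cell-like cells of IgG, and 1 of 185 carried it with anti-CTLA-4 (0.541%). Foxp3 stood at 3.38, 128, 85.7 and 58.1 CPM over T cells of healthy brain, IgG, anti-CTLA-4 and depletion. Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832), the inhibitory receptor bound by the antibody, stood at 13.5, 253, 182 and 157 CPM, against at most 4.97 in B cell-like cells. As a library check, the healthy brain library carried Y-linked Ddx3y at 68.0 CPM and Xist at 2.19, while Xist stood at 950, 889 and 715 in the tumor libraries, so sex differed between healthy brain and tumor.

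**Figure D1:**
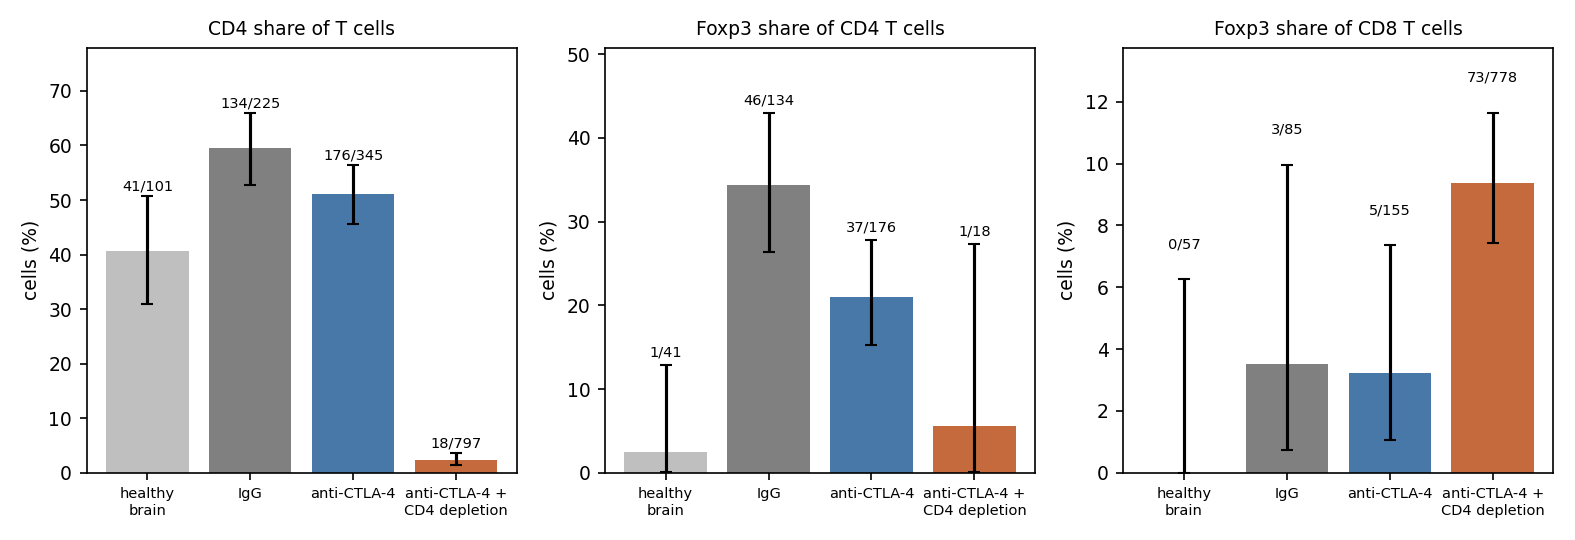
Shares in percent of CD4 cells among T cells, of Foxp3-positive cells among CD4 T cells, and of Foxp3-positive cells among CD8 T cells, 1 bar per library, with exact 95% binomial intervals and the cells counted. The CD4 share was 51.0% with anti-CTLA-4 and 2.26% with added CD4 depletion.

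The comparison of IgG-treated tumor with healthy brain asks how the immune cells of the tumor-bearing brain differ from those at rest. Microglia of the IgG library carried far more antigen presentation and interferon-induced transcripts and less of the homeostatic program. The summed CPM of microglia markers was 35154 in healthy brain and 14390 with IgG, that of monocyte-derived macrophage markers 513 and 2739, and that of monocyte markers 37.5 and 268. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), a chemokine for CXCR3-bearing T cells, stood at 789 CPM against 0 UMIs, at least 1086-fold higher over the floor of 3 counts. The MHC class II chains H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823), H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) and H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674) were 152-fold (95% CI 128 to 182), 127-fold and 125-fold higher. Their invariant chain Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652) was 116-fold (95% CI 106 to 128) higher. The chemokines Ccl5 (151-fold (95% CI 105 to 224)) and Cxcl13 (at least 489.7-fold) and the complement gene C4b (260.2-fold (95% CI 137 to 571)) complete the 8 genes with the largest increase. In these microglia CD8 T cell markers, Ccl5 among them, summed to 86.7 CPM in healthy brain and 1395 with IgG. T cell markers summed to 2.42 and 34.8.

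The 8 largest decreases in these microglia were those of the calprotectin genes S100a9 (56.4-fold (95% CI 21.9 to 208)) and S100a8 (17.8-fold), the platelet glycoprotein Gp9 (22.2-fold), the microglial surface gene Fcrls (8.28-fold (95% CI 7.61 to 9.03)), Gpr165 (71.3-fold (95% CI 12.6 to 2835)), the early-response gene Fosb (16.5-fold), Sema4b (15.7-fold) and Bank1 (8.05-fold). S100a8 and S100a9 are neutrophil genes, and neutrophil-like cells took 56.3% of the CD11b fraction in healthy brain and 11.01% with IgG. By list, all 11 measured members of MHC class II presentation were at least 1.5-fold higher, with a median log2 ratio of 2.09 (95% CI 1.98 to 2.61). The 12 members of MHC class I presentation were too, with a median of 2.01 (95% CI 1.90 to 2.13), led by H2-Q7 (80.0-fold) and the transactivator Nlrc5 (39.6-fold). All 19 interferon-gamma response genes were higher (median 3.35 (95% CI 3.17 to 3.92)), among them the GTPases Iigp1 (266-fold) and Gbp4 (195-fold (95% CI 53.2 to 1624)). All 14 type I interferon response genes were higher as well (median 3.34 (95% CI 3.08 to 3.63)). All 13 homeostatic genes were lower (median -1.18 (95% CI -1.29 to -1.12)), with P2ry12, a purinergic receptor of resting microglia, 4.53-fold (95% CI 4.29 to 4.79) lower and Gpr34 3.86-fold lower. Of 17 disease-associated microglia genes measured, 10 were higher and 1 lower (median 1.43 (95% CI 1.34 to 1.53)); Spp1, encoding osteopontin, was 44.8-fold and Gpnmb at least 32.9-fold higher. Of 14 inflammatory genes, 10 were higher and 1 lower (median 2.07 (95% CI 1.90 to 2.33)).

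In total 336 of 6470 genes passed the size rule upward and 602 downward in microglia (287 cells against 795). The median gene shifted by 0.27 log2 under median-of-ratios scaling, which gave 471 and 300 genes, so the smaller decreases depend on the scaling. Healthy microglia lay mostly in cluster 2 (703 of 795) and IgG microglia in cluster 3 (222 of 287). Within cluster 3 alone the interferon-gamma median was 2.29, the type I interferon median 2.25 and the disease-associated median 0.71. The 83 healthy cells of cluster 3 were shallow, with a median of 1540 UMIs against 5956 with IgG.

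Macrophages of the IgG library, compared with the few monocytes and macrophages of healthy brain, also carried more of these transcripts. The summed CPM of CD8 T cell markers, Ccl5 among them, was 10.1 in healthy brain and 1995 with IgG in these cells, that of T cell markers 4.03 and 45.0, and that of monocyte-derived macrophage markers 37167 and 23456. The largest increases were those of Cxcl9 (at least 171-fold), Arg1, encoding arginase (at least 163-fold), the transglutaminase gene Tgm2 (535-fold (95% CI 95.9 to 21126)), the chemokines Cxcl10 (336-fold (95% CI 60.3 to 13293)) and Ccl5 (319.5-fold (95% CI 109 to 1550.0)), AA467197 (at least 123-fold), H2-Ab1 (110.3-fold (95% CI 70.6 to 183)) and H2-Eb1 (101-fold). The largest decreases were those of Serpinb10 (10.1-fold (95% CI 6.91 to 15.1)), Cdc42ep3 (8.69-fold), Pglyrp1, encoding a peptidoglycan recognition protein (7.97-fold), the transcription factor Klf2 (6.92-fold (95% CI 6.00 to 7.98)), Sort1 (10.4-fold), Svip (9.89-fold), Anxa1 (6.81-fold) and Pdlim1 (7.42-fold). All 11 MHC class II genes were higher (median 3.29 (95% CI 2.38 to 3.78)), as were all 19 interferon-gamma genes (median 3.13 (95% CI 2.70 to 3.71)). Of 13 inflammatory genes 12 were higher (median 3.07 (95% CI 2.62 to 3.54)), and of 13 immunosuppressive genes 10 were higher and 2 lower (median 1.62 (95% CI 1.17 to 1.99)). The size rule was passed by 685 genes upward and 424 downward, and median-of-ratios scaling shifted the median gene by 0.12. The healthy class held 55 cells, 48 of them in a monocyte cluster, and at clustering resolution 0.5 it kept 1 cell, with the MHC class II median at 1.16 and those of the interferon-gamma, inflammatory and immunosuppressive lists at 0. With cells of at least 500 genes the immunosuppressive median was 0.81, and with cells thinned to 1000 UMIs it was 0.44 and the interferon-gamma median 2.26.

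The comparison of anti-CTLA-4 with IgG asks what the antibody changed in the tumor's immune cells. In microglia the differences were few and small beside those between tumor and healthy brain: 37 genes passed the size rule upward and 58 downward (206 cells against 287). The excess of decreases depended on the setting. Leaving ribosomal and mitochondrial genes out of the total gave 28 and 69, no doublet removal 43 and 47, and a ratio of at least 1.5 gave 361 higher and 288 lower. The largest increases were those of Ammecr1l (3.20-fold (95% CI 1.81 to 5.83)), Rab6b (2.83-fold (95% CI 1.83 to 4.45)), the integrin gene Itga9 (2.75-fold), Ddit4, an inhibitor of mTOR signalling (2.73-fold), Thrsp (2.70-fold), Mctp1 (2.67-fold), the heat-shock gene Hspa1b (2.63-fold) and the transporter gene Abca9 (2.27-fold). The largest decreases were those of Flt1, encoding a VEGF receptor (45.9-fold (95% CI 7.96 to 1839)), the chemokines Ccl4 (5.81-fold (95% CI 4.43 to 7.74)) and Ccl7 (4.09-fold), Lpl, encoding lipoprotein lipase (5.49-fold (95% CI 3.48 to 9.11)), the kinase gene Fgr (4.30-fold), Lmnb1, encoding lamin B1 (4.34-fold), Crip1 (4.09-fold) and the antiviral gene Rsad2 (3.81-fold).

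MHC class II presentation had a median log2 ratio of 0.39 (95% CI 0.37 to 0.47) in microglia with anti-CTLA-4, with 3 of 11 members at least 1.5-fold higher and 8 between. H2-DMb2 was 1.75-fold (95% CI 1.246 to 2.46), H2-Eb1 1.54-fold (95% CI 1.49 to 1.59) and H2-Ab1 1.53-fold (95% CI 1.48 to 1.57) higher, below the size rule. Of the homeostatic genes, 3 of 13 were at least 1.5-fold higher and none lower (median 0.40 (95% CI 0.34 to 0.46)), led by Fcrls (1.86-fold (95% CI 1.67 to 2.08)) and Gpr34 (1.84-fold). Of the type I interferon genes 10 of 14 were lower (median -0.67 (95% CI -0.80 to -0.57)), Rsad2 and Mx1 (2.23-fold) the most. Of the disease-associated genes 9 of 17 were lower and none higher (median -0.60 (95% CI -0.72 to -0.52)), among them Gpnmb (14.8-fold (95% CI 3.87 to 126)), Spp1 (3.08-fold (95% CI 2.53 to 3.76)) and the growth factor gene Igf1 (2.70-fold). Of the inflammatory genes 6 of 14 were lower and 2 higher (median -0.42 (95% CI -0.74 to -0.32)); Ccl3 was 2.99-fold lower and Ccl8 4.62-fold higher. The interferon-gamma median was 0.13 (95% CI -0.08 to 0.19) and turned to -0.13 with the mean of per-cell CPM, and the immunosuppressive median of -0.65 turned to 0.15 in thinned cells. The summed CPM of microglia markers was 14390 with IgG and 18981 with anti-CTLA-4, that of monocyte-derived macrophage markers 2739 and 1987, and that of monocyte markers 268 and 166. T cell markers stood at 34.8 and 4.83, and endothelial markers at 45.6 and 14.5. Flt1 is one of these endothelial markers and its decrease carries that fall, so the sum is no separate sign of endothelial RNA. Cluster 11 held 58 of 287 IgG and 13 of 206 anti-CTLA-4 microglia, and cluster 2 held 7 and 31. Those 58 IgG cells were shallow, with a median of 784.5 UMIs, against 2401 for the 13 with anti-CTLA-4. Within cluster 3 alone, where 15 of the higher and 33 of the lower genes were shared, the disease-associated median was -0.42 and the homeostatic median 0.27.

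Macrophages with anti-CTLA-4 differed from those with IgG in few genes, with 33 past the size rule upward and 59 downward (278 cells against 289). The excess of decreases depended on the setting: median-of-ratios scaling gave 42 and 41, and no doublet removal 42 and 37. Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase gene, was 9.00-fold (95% CI 4.71 to 19.3) higher, and Cxcl10 was 2.58-fold (95% CI 2.44 to 2.72) higher. The other large increases were those of the activation gene Cd69 (3.42-fold), Dnase1l3 (2.86-fold), Upp1, encoding uridine phosphorylase (2.55-fold), Gbp6 (ENSMUSG00000104713; 2.75-fold), Dmkn (2.37-fold) and Ccl5 (2.05-fold). The largest decreases were those of the mannose receptor gene Mrc1 (4.08-fold (95% CI 3.04 to 5.53)), the microglial gene Tmem119 (3.74-fold), S100a9 (3.01-fold), S100a8 (2.70-fold), Itga6 (3.58-fold), Pdgfa (2.95-fold), the early-response gene Egr1 (3.62-fold) and Lpl (2.83-fold). Of the interferon-gamma genes 8 of 19 were at least 1.5-fold higher and none lower (median 0.54 (95% CI 0.44 to 0.64)). The type I interferon median was 0.37 (95% CI 0.32 to 0.45), with 4 of 14 members higher. MHC class II presentation stood at 0.21 (95% CI 0.14 to 0.22) with no member past 1.5-fold, and disease-associated genes at -0.26 (95% CI -0.35 to -0.19) with 5 of 17 lower. The summed CPM of neutrophil markers in macrophages was 835 with IgG and 347 with anti-CTLA-4. That of CD8 T cell markers, the chemokines Ccl5 and Ccl4 among them, was 1995 and 4031, while T cell markers summed to 45.0 and 53.2.

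Among T cells, conventional CD4-like cells took 12.7% (95% CI 9.62 to 16.3%) of the CD3 fraction with IgG and 21.6% (95% CI 18.2 to 25.3%) with anti-CTLA-4, and CD8-like cells 9.27% (95% CI 6.64 to 12.499%) and 15.5% (95% CI 12.503 to 18.8%). Regulatory-like cells took 36.8% (95% CI 32.1 to 41.7%) and 26.3% (95% CI 22.6 to 30.2%). The conventional CD4-like difference depended on the clustering. Cluster 5, with conventional CD4 markers, took 22.7% (95% CI 18.7 to 27.0%) with IgG and 28.5% (95% CI 24.7 to 32.5%) with anti-CTLA-4, and these intervals overlap. Of its 93 IgG cells, 29 lay in sub-cluster 13, named as type 2 lymphoid-like, against 3 of 153 with anti-CTLA-4. In CD8-like cells (T sub-clusters 2 and 9, 83 against 38) 35 genes were higher and 21 lower. Sub-cluster 9, with 58 of the 83 and 23 of the 38, had 2 NK markers and 1 CD8 marker among its top 10 genes against all other cells. NK cell markers summed to 5184 CPM with IgG and 7497 with anti-CTLA-4. Higher were Ifitm1 (10.7-fold (95% CI 8.46 to 13.8)), the AP-1 gene Jun (8.78-fold), Fam46a (4.13-fold), the receptor gene Klri2 (3.95-fold), Styk1 (3.93-fold), the integrin gene Itgae (3.27-fold), granzyme A gene Gzma (3.105-fold (95% CI 2.74 to 3.53)) and the interleukin-7 receptor gene Il7r (3.01-fold). Lower were Txk (3.07-fold), Gpr18 (2.85-fold), Nrgn (2.71-fold), Nop58 (2.504-fold), Ankrd10 (2.44-fold), Ccl3 (2.29-fold), the replication gene Mcm6 (2.25-fold) and Uba2 (2.25-fold). Cytotoxicity genes had a median of 0.13 (95% CI -0.11 to 0.42), with 4 of 11 higher and 2 lower; Gzmb was 2.66-fold (95% CI 2.05 to 3.50) higher and Ccl4 1.96-fold lower. The Th1 list stood at 0.15 (95% CI -0.17 to 0.54). Median-of-ratios scaling shifted the median gene by 0.11 and gave 46 higher and 11 lower, leaving out ribosomal and mitochondrial genes gave 30 and 32, and the mean of per-cell CPM 65 and 63. With CD8 cells chosen by transcripts the rule gave 99 genes, 15 of the higher and 0 of the lower ones shared, and in sub-cluster 9 alone 72, 21 and 11 shared.

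In conventional CD4-like cells (116 against 52) 22 genes were higher and 18 lower with anti-CTLA-4, and 29 and 15 under median-of-ratios scaling. The proenkephalin gene Penk was 5.15-fold (95% CI 3.61 to 7.57) and Ccl4 2.82-fold (95% CI 2.46 to 3.25) higher, while Spp1 was 4.10-fold (95% CI 3.25 to 5.21), the lymph-node homing receptor gene Ccr7 2.61-fold (95% CI 1.57 to 4.39) and the type 2 factor Gata3 2.26-fold lower. The other large increases were those of Nrgn, the chemokine Xcl1, Vps37b, the pro-apoptotic Bcl2l11, Fdx1 and Sdha, from 2.30-fold to 3.16-fold, and the other large decreases those of Mir142hg, Tff1, Serpina3f, Chst2 and Tet3, from 2.44-fold to 2.99-fold. Among list members Csf2, encoding GM-CSF, was 25.9-fold (95% CI 9.94 to 95.9) and Ccl3 9.62-fold (95% CI 7.25 to 13.01) higher, from few cells. Csf2 was seen in 7.76% of cells with anti-CTLA-4 and 3.85% with IgG, and Ccl3 in 9.48% and 11.5%. The Th1 list had a median of 0.13 (95% CI -0.06 to 0.37), with 1 of 13 members higher, and cytotoxicity 0.39 (95% CI 0.26 to 0.88), with 3 of 7 higher and a median of 1.70 in thinned cells. In these cells the summed CPM of CD8 T cell markers, Ccl4 among them, was 2118 with IgG and 3982 with anti-CTLA-4. That of NK cell markers was 1618 and 2285. Regulatory-like cells (141 against 151) differed in 15 genes upward and 10 downward (13 and 14 under median-of-ratios scaling): the metallothionein gene Mt1 was 3.63-fold (95% CI 2.32 to 5.84), the inhibitory receptor gene Lag3 2.42-fold (95% CI 1.72 to 3.44) and Gzmb 2.13-fold higher. Plac8, Gadd45b, Socs3, Sh3bp1 and Penk were 2.10-fold to 2.37-fold higher, and Max, Elovl5, Dr1, Nr1h2, Arrb2, Tomm40, Ctr9 and Zbtb7b were 2.01-fold to 2.34-fold lower. Foxp3 in these cells stood at 428 CPM with IgG and 414 with anti-CTLA-4, and Ctla4 at 558 and 436.

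The comparison of added CD4 depletion with anti-CTLA-4 alone asks which of these states were also seen without CD4 T cells. Microglia of the depletion library carried much less MHC class II and interferon-gamma-induced RNA. H2-Aa was 7.78-fold (95% CI 7.43 to 8.15), H2-Eb1 7.69-fold, H2-Ab1 7.53-fold and Cd74 6.38-fold (95% CI 6.22 to 6.55) lower. Cxcl9 was 7.38-fold (95% CI 6.60 to 8.26) lower, and Serpina3f (10.6-fold), the ribonuclease gene Rnase6 (6.34-fold) and H2-Oa (6.19-fold) complete the 8 largest decreases. Ciita, the transactivator of MHC class II genes, was 15.8-fold (95% CI 5.51 to 61.8) lower. The largest increases were those of S100a9 (80.8-fold (95% CI 14.3 to 3209.8)), S100a8 (54.8-fold (95% CI 15.02 to 455)), the metallothionein gene Mt2 (25.8-fold (95% CI 6.97 to 215)), the chemokines Ccl4 (8.38-fold (95% CI 6.45 to 11.1)) and Ccl3 (7.16-fold), Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050; 7.17-fold (95% CI 5.99 to 8.64)), Wfdc17 (7.16-fold) and Fn1, encoding fibronectin (6.85-fold).

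By list, 9 of 11 MHC class II genes were at least 1.5-fold lower, 1 lay between and 1, Ifi30, was 1.52-fold (95% CI 1.40 to 1.64) higher (median -2.67 (95% CI -2.81 to -2.49)). Of the MHC class I genes 8 of 12 were lower and none higher (median -0.89 (95% CI -0.98 to -0.74)). Of the interferon-gamma genes 18 of 19 were lower (median -1.69 (95% CI -1.82 to -1.38)), among them Tgtp2 (4.50-fold), Igtp (4.04-fold) and Iigp1 (3.90-fold (95% CI 3.34 to 4.55)). Homeostatic genes were lower in 9 of 13 cases (median -0.92 (95% CI -1.01 to -0.82)), P2ry13 (2.68-fold) and Gpr34 (2.62-fold) the most. Of the disease-associated genes 8 of 17 were higher and none lower (median 0.37 (95% CI 0.34 to 0.71)), with Gpnmb 12.2-fold (95% CI 3.22 to 103) and Igf1 4.09-fold higher. Of the inflammatory genes 8 of 15 were higher and 3 lower (median 0.61 (95% CI 0.16 to 0.76)): Il12b, encoding a subunit of interleukin-12, was 29.1-fold (95% CI 7.89 to 243) higher and Ccl8 6.27-fold lower. The proliferation list had a median of 0.75 (95% CI 0.41 to 1.49), with no member past the size rule, and the type I interferon median of -0.09 changed sign between scalings.

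The size rule was passed by 181 genes upward and 357 downward (456 cells against 206), and median-of-ratios scaling shifted the median gene by 0.17 and gave 296 and 201. Leaving out ribosomal and mitochondrial genes gave 254 and 223. Depletion microglia lay mostly in cluster 11 (273 of 456) and those of anti-CTLA-4 in cluster 3 (162 of 206); within cluster 3 alone 61 genes were higher and 72 lower, with medians of -2.25 for MHC class II, -0.96 for interferon-gamma, -0.32 for homeostatic genes and 1.46 for proliferation. S100a8 and S100a9 were higher in the library in which neutrophil-like cells took 32.8% of the CD11b fraction, against 10.7% with anti-CTLA-4 (385 of the 503 with depletion in cluster 10). In these microglia the summed CPM of monocyte markers was 166 with anti-CTLA-4 and 676 with depletion, and that of neutrophil markers 233 and 271. Microglia markers summed to 18981 and 12187, and markers of type 2 conventional dendritic cells, H2-DMb2 among them, to 70.8 and 13.2.

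**Figure D2:**
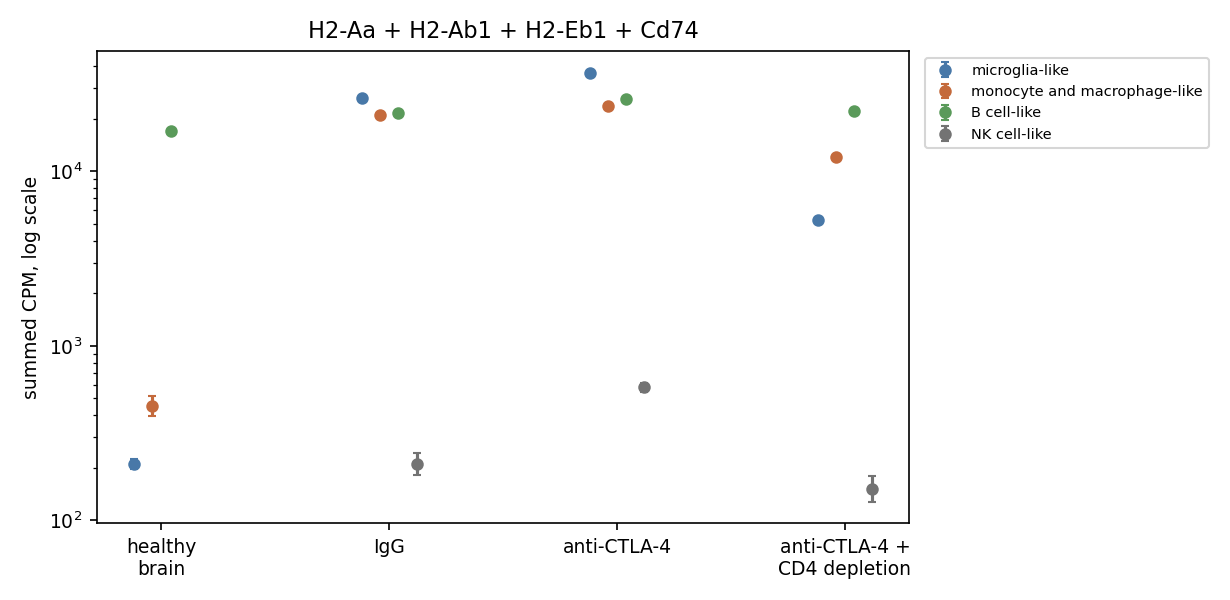
Summed CPM of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 (log axis) in 4 cell types with at least 50 cells in a library, 1 point per library, with 95% counting intervals. Microglia stood at 212 in healthy brain, 26397 with IgG, 36699 with anti-CTLA-4 and 5247 with added depletion.

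Of the 37 microglia genes higher with anti-CTLA-4 than with IgG, 17 were lower again with added depletion, among them Rab6b, Thrsp, Hspa1b, Mctp1, Itga9, Abca9 and Ammecr1l. Thrsp stood at 18.5 CPM with IgG, 49.9 with anti-CTLA-4 and 13.2 with depletion, and Abca9 at 67.3, 153 and 54.3. Of the 58 lower genes, 29 were higher again. Independent lists would share 2.10 and 0.872 genes, and Poisson simulations of unchanged libraries shared at most 3 in the first direction. Both ratios use the same anti-CTLA-4 library, so any peculiarity of that 1 library enters both, and with cluster 3 alone 3 genes followed the first pattern. Neither baseline takes account of the mix of clusters. Cluster 2, where most healthy microglia lay, held 7 of 287 microglia with IgG, 31 of 206 with anti-CTLA-4 and 20 of 456 with depletion.

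Macrophages of the depletion library had lower interferon-induced and antigen presentation RNA and more RNA of neutrophil markers than with anti-CTLA-4 alone. Cxcl9 was 8.65-fold (95% CI 8.15 to 9.18), Nos2 14.4-fold (95% CI 8.46 to 26.0), the GTPase gene Iigp1 8.24-fold, Irg1, needed for itaconate production, 5.94-fold and Ccl5 5.54-fold lower, followed by Cnn3 (6.67-fold), Ly6i (5.49-fold) and the signalling inhibitor Socs1 (4.74-fold). Higher were Wfdc21 (105-fold), Lcn2, encoding lipocalin 2 (70.8-fold (95% CI 35.8 to 164)), S100a8 (17.8-fold), S100a9 (13.7-fold), Klf9 (13.9-fold), the decoy receptor gene Il1r2 (11.02-fold), the serum amyloid gene Saa3 (10.9-fold) and Rgs1 (10.6-fold). The summed CPM of neutrophil markers in macrophages was 347 with anti-CTLA-4 and 4048 with depletion. That of CD8 T cell markers, the chemokines Ccl5 and Ccl4 among them, was 4031 and 754, while T cell markers summed to 53.2 and 17.2. Markers of type 1 conventional dendritic cells summed to 940 and 461, and those of type 2, H2-DMb2 among them, to 152 and 49.6. Monocyte-derived macrophage markers summed to 24778 and 17713. All 19 interferon-gamma genes were lower (median -1.79 (95% CI -1.87 to -1.67)), as were 9 of 11 MHC class II genes (median -1.004 (95% CI -1.03 to -0.97)), 11 of 12 MHC class I genes (median -0.98 (95% CI -1.03 to -0.93)) and 10 of 14 type I interferon genes (median -0.78 (95% CI -0.82 to -0.70)). Of 15 inflammatory genes 9 were lower and 3 higher (median -0.81 (95% CI -0.88 to -0.47)). Cxcl2 was 43.3-fold higher, and it was also the leading gene of neutrophil-like cluster 10 over all other cells. Costimulation genes had a median of -0.83 (95% CI -1.04 to -0.67) and hypoxia and glycolysis genes one of -0.79 (95% CI -0.89 to -0.72). The size rule was passed by 185 genes upward and 347 downward (792 cells against 278), by 223 and 272 under median-of-ratios scaling and by 241 and 255 with ribosomal and mitochondrial genes left out. Cluster 9, with 451 of the 792 depletion macrophages, held none of the 278 with anti-CTLA-4; in cluster 1 alone 29 genes were higher and 126 lower, the interferon-gamma median was -0.96 and the type I interferon median -0.02.

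**Figure D3:**
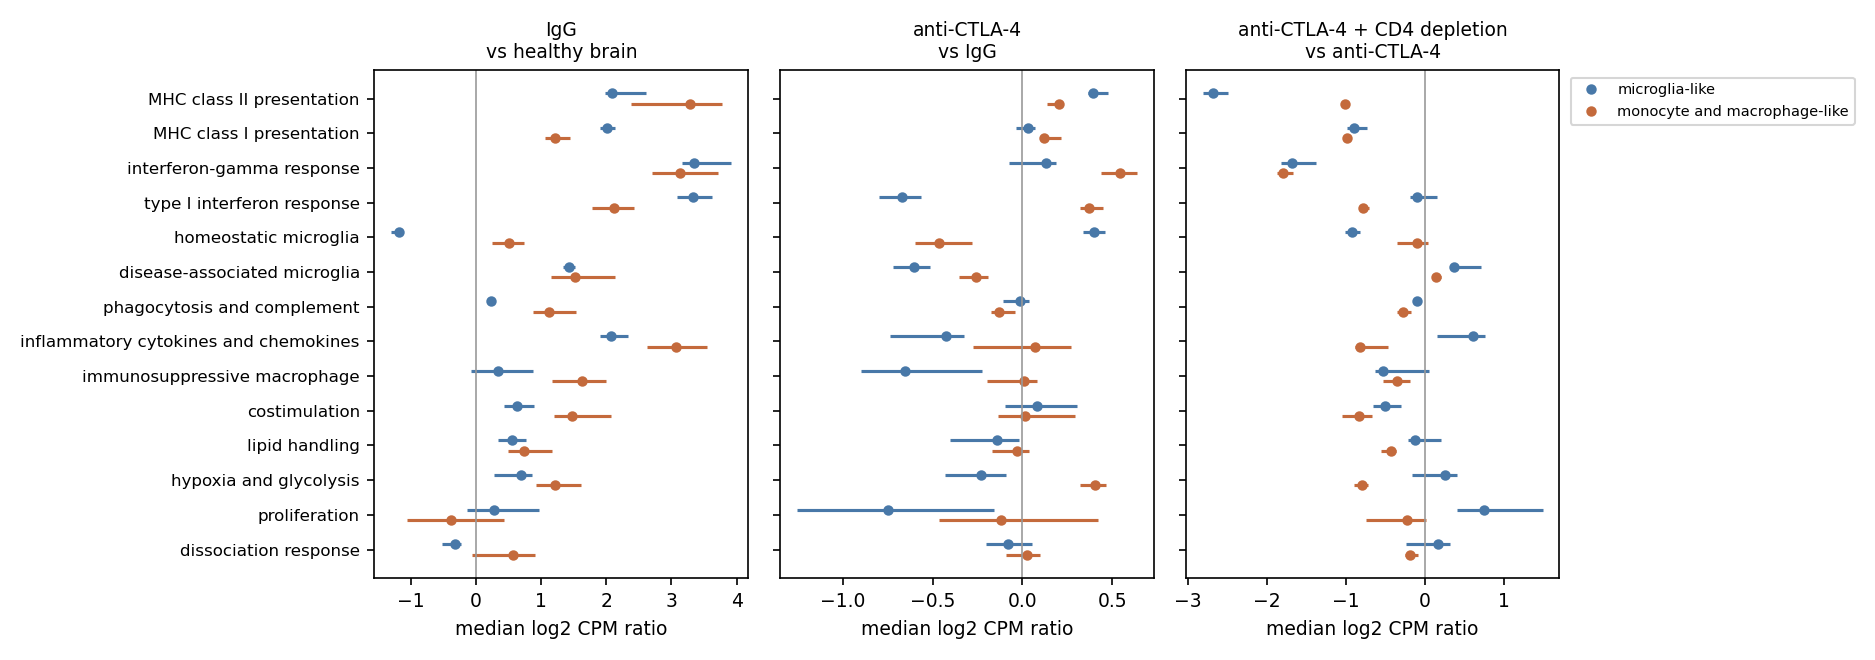
Median log2 CPM ratio of each gene list in microglia and macrophages, 1 panel per comparison, with lines for 95% counting intervals. With added depletion the interferon-gamma median was -1.69 in microglia and -1.79 in macrophages; medians of 9 lists (MHC class I, interferon-gamma, type I interferon, homeostatic, phagocytosis, immunosuppressive, costimulation, lipid handling and dissociation) changed sign under other scalings in at least 1 comparison.

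CD8-like T cells of the depletion library (236 against 83) carried more transcripts of naive and memory cells: 68 genes were higher and 75 lower. Klf2, a transcription factor of recirculating T cells, was 6.31-fold (95% CI 4.30 to 9.60) higher, followed by Slamf6 (5.75-fold), the naive-cell factor Lef1 (5.35-fold), Klf3 (5.64-fold), the egress receptor gene S1pr1 (4.64-fold (95% CI 2.69 to 8.58)), Rasgrp2 (5.08-fold), Racgap1 (5.48-fold) and Pdlim1 (4.71-fold). Lower were Klri2 (13.8-fold), Ifitm1 (7.14-fold (95% CI 6.38 to 8.01)), Styk1 (11.7-fold), AA467197 (6.87-fold), Csf1, encoding M-CSF (6.21-fold), H2-Eb1 (4.17-fold), Chchd10 (3.65-fold) and Irf8 (3.40-fold). The 4 summed MHC class II genes stood at 306 CPM with anti-CTLA-4 and 104 with depletion in these cells, below NK cell-like cells, which should lack them (581 and 152), so this MHC class II RNA was not above background. Of the naive and memory genes 8 of 9 were higher (median 2.21 (95% CI 1.63 to 2.58)), and of the interferon-gamma genes 7 of 16 were lower (median -0.55 (95% CI -0.79 to -0.23)). Cytotoxicity genes had a median of -0.04 (95% CI -0.22 to 0.08), and -0.70 with cells chosen by transcripts: Gzma was 2.90-fold (95% CI 2.68 to 3.13) and Gzmb 2.0003-fold lower, and Klrg1, a receptor of effector cells, 27.1-fold (95% CI 4.60 to 1094) higher. The mix of CD8 sub-clusters differed, with 185 of 236 depletion cells in sub-cluster 2 and 58 of 83 anti-CTLA-4 cells in sub-cluster 9. Sub-cluster 2 alone (185 against 25) shared 13 of the higher and 3 of the lower genes. There the naive and memory median was 0.83. NK cell markers, Klri2 among them, summed to 7497 CPM with anti-CTLA-4 and 4424 with depletion. In sub-cluster 9 alone (51 against 58) 84 genes passed, 7 and 18 shared, with medians of -0.76 for interferon-gamma and -0.49 for cytotoxicity. With CD8 cells chosen by transcripts (705 against 150) the naive and memory median was 0.64. In the CD8-like class it was 1.36 without doublet removal, 1.5 in thinned cells and 1.62 with the mean of per-cell CPM. That class left out many CD8 T cells, as unnamed T sub-clusters took 54.1% of the CD3 fraction with depletion and 30.7% with anti-CTLA-4.

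Regulatory-like cells took 13.8% (95% CI 11.9 to 15.9%) of the CD3 fraction with depletion, against 26.3% with anti-CTLA-4, and nearly lacked Cd4 RNA. In them Cd4 was 36.7-fold (95% CI 12.3 to 181) lower, and Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173), encoding the CD8 alpha chain, stood at 267 CPM against 1.47, 182-fold (95% CI 32.3 to 7238) higher. Cd8b1 was 10.8-fold (95% CI 6.74 to 18.3) and Gzmb 4.32-fold (95% CI 3.86 to 4.85) higher, while Penk was 30.4-fold, Lag3 28.0-fold (95% CI 10.7 to 104) and the Notch pathway factor Rbpj 5.45-fold lower. Tstd3, Ltb4r1, AA467197, Cd79b and Ifit1 were 3.41-fold to 5.03-fold higher, and Itgb8, Lilrb4a, Itih5 and Mt1 were 5.82-fold to 11.4-fold lower. B cell markers summed to 33.7 CPM with anti-CTLA-4 and 84.9 with depletion in these cells. Cd79b itself makes up most of that sum, so the sum is no separate sign of B cell RNA. The type I interferon list had a median of 0.74 (95% CI 0.61 to 1.26), with 10 of 13 members higher, Mx1 by 3.86-fold (95% CI 1.52 to 11.6) and Ifit1 by 3.41-fold (95% CI 2.48 to 4.76). The checkpoint and exhaustion list stood at -0.60 (95% CI -0.86 to -0.37) and at -1.54 in thinned cells. In all, 66 genes were higher and 77 lower (165 cells against 141), and 49 and 102 with ribosomal and mitochondrial genes left out of the total. Depletion cells lay mostly in T sub-cluster 3 (145 of 165) and anti-CTLA-4 cells in sub-cluster 1 (113 of 141, 28 in sub-cluster 3). Sub-cluster 3 alone shared 13 of the higher and 4 of the lower genes, and sub-cluster 1 alone 6 and 16. Within sub-cluster 3 alone Cd8a stood at 285 CPM against 0 UMIs and Gzmb was 2.19-fold (95% CI 1.85 to 2.61) higher. There the type I interferon median turned to -0.30 and the checkpoint median to 0.19, and in sub-cluster 1 alone the type I interferon median was -0.26. A Foxp3 UMI was seen in 3.53% (3 of 85, 95% CI 0.734 to 9.97%) of CD8 T cells with IgG, 3.23% (5 of 155, 95% CI 1.06 to 7.37%) with anti-CTLA-4 and 9.38% (73 of 778, 95% CI 7.43 to 11.7%) with depletion, a share chosen for reporting after it was seen, while 0 of 136 B cell-like cells of the last library carried one (up to 2.21% allowed by 3 counts). Thinned to 1000 UMIs per cell, these shares were 1.69%, 2.5% and 3.56%.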

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

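The tests of free Cd8a RNA, of droplets with a pair of T cells, of macrophages counted as microglia, of the mix of microglia clusters and of shallow cells were chosen only after the results they measure were seen; the tests of MHC class II RNA in NK cell-like cells and of a shift of all cells were written before their results were seen.

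Cells like gamma-delta T cells or type 3 lymphoid cells, which no comparison used, took 8.10% (95% CI 6.62 to 9.80%) of the CD3 fraction with added depletion, 5.40% (95% CI 3.65 to 7.66%) with anti-CTLA-4 and 1.95% (95% CI 0.846 to 3.81%) with IgG. The intervals with depletion and anti-CTLA-4 overlapped. Conventional CD4-like cells took 21.6% of this fraction with anti-CTLA-4 and 3.34% with depletion. Such a loss by itself raises the shares of the other T cell classes. The groups lay in different sub-clusters: sub-cluster 11 held 66 of 97 such cells with depletion and 1 of 29 with anti-CTLA-4, and in sub-cluster 10 the shares were 2.59% (95% CI 1.77 to 3.66%) and 5.21% (95% CI 3.49 to 7.45%). Neutrophil-like cells, also unused, took 32.8% (95% CI 30.5 to 35.2%) of the CD11b fraction with depletion, 10.7% (95% CI 7.97 to 13.98%) with anti-CTLA-4, 11.01% (95% CI 8.26 to 14.3%) with IgG and 56.3% (95% CI 50.5 to 62.0%) in healthy brain. Of these, 385 of 503 with depletion lay in cluster 10, with none of anti-CTLA-4 or IgG, and 169 of 170 in healthy brain lay in cluster 15. In cluster 14 the shares were 7.11% (95% CI 5.87 to 8.51%) with depletion and 9.79% (95% CI 7.18 to 12.97%) with anti-CTLA-4. The inflammatory list went opposite ways in the 2 myeloid classes with depletion against anti-CTLA-4, with medians of 0.61 (95% CI 0.16 to 0.76) in microglia and -0.81 (95% CI -0.88 to -0.47) in macrophages; the difference was not tested.

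Regulatory-like cells with Cd8a were a feature of the depletion library. Free Cd8a RNA is argued against, since a Cd8a UMI was seen in 18.3% of regulatory-like cells thinned to 1000 UMIs (33.9% unthinned) and in 0 of 129 thinned B cell-like cells of the same library. Droplets with 1 regulatory and 1 CD8 T cell drawn at random are argued against by Gzmk, at 0 CPM in the 47 T cells with Foxp3 and Cd8a in any sub-cluster (exact 95% upper limit 15.1), 43 of them regulatory-like, against 82.0 in the 705 T cells with Cd8a or Cd8b1 and without Cd4 and Foxp3. Their median depth of 4764 UMIs lay above that of regulatory-like (3538) and CD8-like cells (4178.5), so pairs with a CD8 cell of a type without Gzmk stay open. A regulatory program in CD8 T cells that remain when CD4 T cells are removed may be a candidate explanation, untested beyond these values, and 1 library cannot part it from a property of that pool.

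MHC class II RNA was lower in microglia with added depletion. Free RNA that differs between libraries is argued against, since NK cell-like cells of the anti-CTLA-4 library carried the 4 genes at 1.58% (95% CI 1.49 to 1.68%) of the microglia level. Macrophages counted as microglia there are argued against by their lower level, 0.649 (95% CI 0.642 to 0.657) of that in microglia. Markers of type 2 conventional dendritic cells in microglia also fell, from 70.8 to 13.2 CPM. They include H2-DMb2, itself on the MHC class II list, so this fall is no separate sign of such cells. Dendritic cells counted as microglia were not tested. Another mix of clusters cannot be the whole cause, since within cluster 3 alone the depletion library stood at 0.194 (95% CI 0.189 to 0.198) of anti-CTLA-4. A need for CD4 T cells may be a candidate explanation; handling that acts on microglia alone, the gate used, and differences between single pools stay open.

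Clusters 9 (macrophage-like) and 10 (neutrophil-like) came almost only from the depletion library, as did T sub-clusters 5 (190 of 194 cells), 11 (66 of 67) and 14 (21 of 21; 23.1% of its T cells in all). Shallow cells are argued against for cluster 9, whose median of 7930 UMIs was 182% of the library's (lower 95% limit 174%), and for the others by cells of IgG and anti-CTLA-4 no deeper than their median: 0 of 23 such neutrophil-like cells (exact 95% upper limit 14.8%) lay in cluster 10, against 75.7% with depletion, and 1.23% of 162 such T cells (95% CI 0.1499 to 4.39%) in the T sub-clusters, against 30.5%. A shift of all its cells stays open: with B cell-like and NK cell-like cells each clustered on their own, 19.9% of its 417 such cells (95% CI 16.2 to 24.1%) lay in sub-clusters at least 90% its own. These were 78 of 281 NK cell-like cells and 5 of 136 B cell-like cells. A batch effect of that library and a state of these cells without CD4 T cells may both be candidate explanations, and a single library per group leaves them open.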

How the results depend on the processing

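The choices of other clusters, sub-clusters or transcripts per class were made after seeing the data; the other alternatives were planned. Comparisons are named by their first group, and every value here is a count of genes past the size rule, a median log2 ratio or a percentage.

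With 1 pool per group, no alternative can replace replicates, and none was there to leave out. No paired analysis was possible because each group was a single pool with no shared animal. Over 139 list medians and 1256 alternative values, 1037 stayed inside the counting interval, 213 moved and 6 reversed, with a median shift of 0.05. Reversed means a changed sign of a median of at least 1.5-fold; with smaller medians counted too, 95 of the 1256 values changed sign. Of the 45 medians of at least 1.5-fold, 380 of 393 alternative values kept their sign. All 12 gene counts (higher and lower genes together) stayed within 1.5 times with at least 500 genes, without doublet removal and with median-of-ratios scaling. The same held without ribosomal and mitochondrial genes and at both resolutions, though at resolution 0.5 the macrophage counts against healthy brain rest on 1 cell. T cells were clustered again at resolution 1 under every setting. At resolution 0.5 the T cell counts and list medians therefore equalled the main ones by construction, and these medians are among the 1037. They do not test the choice of resolution. The split into higher and lower genes moved further with the scaling, for microglia with IgG from 336 and 602 to 471 and 300. Depth limits classes of few cells, such as 38 CD8-like cells with IgG, and genes under 50 UMIs were not tested.

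All 12 counts moved where the rule itself was loosened or the counts thinned, as these settings pass more genes or leave fewer UMIs by construction. A ratio of at least 1.5 gave microglia 2414 (IgG), 649 (anti-CTLA-4), 1759 (depletion), macrophage 2186 (IgG), 569 (anti-CTLA-4), 1699 (depletion), CD8 T cell 296 (anti-CTLA-4), 550 (depletion), conventional CD4 T cell 290 (anti-CTLA-4), regulatory T cell 290 (anti-CTLA-4), 642 (depletion), 217 higher then lower. At least 20 UMIs and no minimum share gave microglia 1855 (IgG), 394 (anti-CTLA-4), 1171 (depletion), macrophage 1788 (IgG), 336 (anti-CTLA-4), 1094 (depletion), CD8 T cell 398 (anti-CTLA-4), 466 (depletion), conventional CD4 T cell 347 (anti-CTLA-4), regulatory T cell 282 (anti-CTLA-4), 553 (depletion), 87 higher then lower. Thinned cells gave microglia 268 (IgG), 24 (anti-CTLA-4), 165 (depletion), macrophage 211 (IgG), 19 (anti-CTLA-4), 169 (depletion), CD8 T cell 6 (anti-CTLA-4), 29 (depletion), conventional CD4 T cell 9 (anti-CTLA-4), regulatory T cell 9 (anti-CTLA-4), 31 (depletion), 3 higher then lower. Thinned anti-CTLA-4 calls were mostly other genes: microglia shared 0 higher and 0 lower genes with the main result, macrophages 2 and 0, regulatory T cells 1 and 0. Microglia shared 87 and 116 with IgG and 29 and 58 with depletion. For the moves that follow, the cause was not tested unless one is named. The mean of per-cell CPM gave microglia 252 (anti-CTLA-4), macrophage 148 (anti-CTLA-4), CD8 T cell 128 (anti-CTLA-4), regulatory T cell 44 (anti-CTLA-4), 38 higher then lower. The chosen clusters or transcripts gave microglia 133 (depletion), macrophage 155 (depletion), CD8 T cell 99 (anti-CTLA-4), 3 higher then lower. T sub-cluster 9 alone gave CD8 T cell 84 (depletion); in sub-clusters 1, 2 and 3 no count moved past 1.5 times, but most genes differed: of the 66 higher and 77 lower genes of regulatory T cells with depletion, sub-cluster 1 shared 6 and 16 and sub-cluster 3 shared 13 and 4.

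With at least 500 genes per cell medians were microglia MHC class II 0.36 (anti-CTLA-4). With the mean of per-cell CPM medians were macrophage MHC class II -1.04 (depletion) and 0.30 (anti-CTLA-4), microglia MHC class II -2.46 (depletion), microglia homeostatic -0.997 (IgG) and -0.77 (depletion), microglia interferon-gamma -0.13 (anti-CTLA-4). With median-of-ratios scaling medians were macrophage MHC class II -0.94 (depletion) and 0.28 (anti-CTLA-4), microglia MHC class II 0.35 (anti-CTLA-4), microglia homeostatic -0.91 (IgG) and -0.75 (depletion). Without doublet removal medians were macrophage MHC class II -0.95 (depletion), microglia interferon-gamma 0.20 (anti-CTLA-4). At resolution 0.5 medians were macrophage MHC class II 1.16 (IgG), macrophage interferon-gamma 0 (IgG) and -1.87 (depletion). Without ribosomal and mitochondrial genes medians were macrophage MHC class II -0.91 (depletion), microglia MHC class II 0.34 (anti-CTLA-4), microglia homeostatic -1.06 (IgG) and -0.78 (depletion). In thinned cells medians were macrophage MHC class II -0.95 (depletion) and 0.13 (anti-CTLA-4), macrophage interferon-gamma 2.26 (IgG), microglia homeostatic -1.01 (IgG) and -0.63 (depletion), microglia interferon-gamma 3.05 (IgG) and -1.28 (depletion). With the chosen clusters medians were macrophage MHC class II -0.86 (depletion), macrophage interferon-gamma -0.96 (depletion), microglia MHC class II 1.82 (IgG) and -2.25 (depletion) and 0.51 (anti-CTLA-4), microglia homeostatic -0.77 (IgG) and -0.32 (depletion) and 0.27 (anti-CTLA-4), microglia interferon-gamma 2.29 (IgG) and -0.96 (depletion).

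Clusters in place of transcripts gave CD4 shares of 4.93% (healthy brain), 49.5% (IgG) and 17.1% (depletion), and regulatory shares of 85.7%, 74.4%, 54.9% (anti-CTLA-4) and 80.5%; regulatory-like clusters count as CD4 there. Thinned cells gave CD4 shares of 25.5% (healthy brain), 44.0% (IgG) and 34.9% (anti-CTLA-4) and regulatory shares of 0%, 16.7%, 6.15% and 0% (healthy brain, IgG, anti-CTLA-4, depletion), as fewer UMIs per cell leave fewer cells with a transcript. Medians of at least 1.5-fold reversed in 5 lists: microglia immunosuppressive with anti-CTLA-4 at 0.15 in thinned cells, macrophage lipid handling with IgG at -0.24 at resolution 0.5, CD8 regulatory T with anti-CTLA-4 at 0.00137 with CD8 cells by transcripts, regulatory T cell type I interferon with depletion at -0.26 in T sub-cluster 1 and -0.30 in 3, and regulatory T cell checkpoint with depletion at 0.19 in 3.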

Other observations

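The values in this part were planned with the lists, except the shares and sums by cluster, which were chosen after the results were seen.

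These lists are outside the account above. Phagocytosis and complement genes had a median log2 ratio of 0.23 (95% CI 0.17 to 0.29) in microglia and 1.13 (95% CI 0.87 to 1.54) in macrophages for IgG against healthy brain, with the complement genes C1qc (55.0-fold) and C1qa (51.4-fold) among the most raised in macrophages, and 0.11 at resolution 0.5. In microglia C3 (176-fold (95% CI 59.4 to 858)) and Cd36 (62.0-fold) were the most raised. Lipid handling stood at 0.55 (95% CI 0.34 to 0.77) in microglia with IgG and at -0.43 (95% CI -0.55 to -0.36) in macrophages with depletion, where Fabp4, a fatty-acid carrier gene, was 8.87-fold (95% CI 2.89 to 36.2) lower and Abcg1 2.09-fold lower. Costimulation stood at 0.63 (95% CI 0.43 to 0.89) in microglia with IgG, with Cd40 94.2-fold (95% CI 16.01 to 3808) higher, and at 1.48 (95% CI 1.20 to 2.08) in macrophages with IgG, where Cd40 was 9.77-fold (95% CI 3.76 to 36.2) higher. Hypoxia and glycolysis genes in macrophages stood at 1.21 (95% CI 0.93 to 1.61) with IgG, with Vegfa at least 10.53-fold higher. With anti-CTLA-4 they stood at 0.40 (95% CI 0.32 to 0.47), with Pgk1 1.89-fold (95% CI 1.53 to 2.34) higher. Dissociation-response genes, a sign of handling, stood at -0.31 (95% CI -0.52 to -0.22) in microglia with IgG, 0.17 (95% CI -0.24 to 0.32) with depletion and -0.18 (95% CI -0.25 to -0.08) in macrophages with depletion. In macrophages with IgG they stood at 0.57 (95% CI -0.05 to 0.91), and at -0.13 with the mean of per-cell CPM. At resolution 0.5, where 1 healthy cell is left, the costimulation, hypoxia and dissociation medians of these macrophages were 0. The regulatory T list stood at 0.19 (95% CI 0.07 to 0.27) in regulatory-like cells with anti-CTLA-4 and at -0.32 (95% CI -0.46 to -0.21) with depletion, where Izumo1r (2.20-fold) and Tnfrsf4 (2.14-fold) were the lowest.

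Cells like type 2 lymphoid cells took 7.07% (95% CI 4.79 to 10.0%) of the CD3 fraction with IgG and 0.559% (95% CI 0.115 to 1.62%) with anti-CTLA-4. Patrolling monocyte-like cells took 11.7% (95% CI 8.85 to 15.04%) of the CD11b fraction with IgG, 15.03% (95% CI 11.8 to 18.7%) with anti-CTLA-4 and 5.09% (95% CI 4.04 to 6.31%) with depletion. Type 2 conventional dendritic-like cells took 0.662% (95% CI 0.0803 to 2.37%) in healthy brain, 12.4% (95% CI 9.45 to 15.8%) with IgG, 10.9% (95% CI 8.17 to 14.2%) with anti-CTLA-4 and 10.4% (95% CI 8.95 to 12.1%) with depletion. B cell-like cells carried the 4 MHC class II genes at 16942, 21637, 25877 and 22209 CPM in healthy brain, IgG, anti-CTLA-4 and depletion, while macrophages stood at 455, 21194, 23819 and 12052. NK cell-like cells stood at 211 with IgG, 581 with anti-CTLA-4 and 152 with depletion.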
